A study of Arabidopsis thaliana with 6 samples.

How the data were processed

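RNA was taken from whole seedlings of Col-0 at 7 days, in 3 WT and 3 mir163 libraries. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit. The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat and Cufflinks and the genome build TAIR10, without roles or order. Per the file headers, the authors' values are FPKM, that is, fragments per kilobase of transcript scaled to the total of mapped fragments, with 1 column for WT and 1 for mir163. The authors' log2 fold change equals the log2 ratio of these FPKM columns, and is infinite for the 11 genes listed at 0 in a genotype. The authors' deposited p-value is unadjusted, and every value is a whole multiple of 5e-05 within a tolerance of 1e-06 steps. How the libraries were combined into 1 value per genotype, which test gave the p-values and whether it was two-sided are not given in the sources used here. The library kit as named does not say whether strand was kept, so overlapping and antisense genes cannot be told apart in these values. Plain FPKM is relative to the total of each library, so a change in a few abundant transcripts would shift all others. Whether a further scaling between libraries was applied is not given in the sources used here. The FPKM sum was 1136680 in WT and 1036970 in mir163.

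Depth is unknown, since no read counts were analysed here and each value combines libraries. No interval or detection limit that needs a depth was therefore given. The labels number the replicates in each group, and call them biological. The authors' p-values measure only the spread that their own test used.

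Before the data were examined, limma on log2(FPKM + 1) per library had been chosen, with camera for gene lists. With 1 value per genotype neither could be fitted. In their place, the authors' p-values were adjusted by Benjamini-Hochberg over all genes tested, and over each gene list alone, at a threshold of 0.05. A gene was tested where its FPKM was at least 1 in a genotype, which kept 19264 genes and left out 691. Folds are plain FPKM ratios, and none is given against a genotype listed at 0. List medians are on the log2(FPKM + 1) scale, which understates the change of low genes. For each list the median was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins (seed 163). Percentiles under 2.5 or over 97.5 were counted as outside the central 95%.

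The 23 lists named by pathway, cell type or regulator, and the list of 10 annotated neighbours of MIR163 on each side, were fixed before the data were examined. They hold 381 members, of which 325 were in the table. The rule for named genes was fixed then too: MIR163 and the 6 miR163 targets; the 10 largest changes in each direction past the adjusted threshold with separate replicates and a mean of at least 1; in each list up to 4 members past the threshold, or else the 2 with the highest mean; and neighbours of MIR163 past the threshold. As no gene passed over all genes, the largest changes were taken instead among genes at an unadjusted p under 0.05 with a mean of at least 1, ranked by the change in log2(FPKM + 1). That change, and the choice of BOA, OLEO2, EM6, CCA1, ELF3, TOC1, GI, GRP7, GRP8, AT1G53540 and AT4G10250 as further examples, was made after values were seen. For the ethylene list, 1 of the genes that the rule names is not reported here.

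Gene symbols and coordinates come from the RefSeq annotation of TAIR10.1, and 19661 of the gene identifiers matched it, while 294 did not. Coordinates are for TAIR10.1 only. Sites for mature miR163 were sought in all annotated transcripts, allowing at most 4 differences (mismatches, and at most 1 gap of 1 base). The gap was allowed after a search without gaps had missed the known targets.

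The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data for 19264 genes in the comparison of mir163 with WT. The adjustment recovered 199 of 200 changed genes and called 3 unchanged ones. The simulated p-values had no lowest step and were uniform for unchanged genes, unlike the authors' p-values. These counts therefore check the calculation only, not the power in these data. Of unchanged lists of 15 genes, 3% fell outside the central 95%, and 100% of lists shifted by 0.5 on the log2 scale were found. These lists held unrelated genes, and smaller shifts were not simulated. The alternatives tried were no filter, a minimum FPKM of 5, a fold of at least 2, pseudocounts of 0.1 and 5, median-ratio scaling, quantile normalization and a rescaling of the p-values. The replicate block, leaving out each library, library weights, camera with estimated correlation and fry need values per library and were not run.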

Results

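Gene expression was measured by RNA sequencing in whole 7-day-old seedlings of Arabidopsis thaliana, accession Col-0, grown in long days without treatment. The labels name 3 wild-type (WT) libraries and 3 libraries of the mir163 mutant, 6 in all, and call them biological replicates. miR163 is a microRNA that guides cleavage of mRNAs of SABATH methyltransferases, enzymes that transfer a methyl group to small carboxylic acids and related metabolites. The authors' deposited table gives 19955 genes with 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped total) per genotype, a log2 fold change and an unadjusted p-value. No value per library was analysed here, so no spread between replicates can be given for any gene, and the depth of the libraries is unknown. The median FPKM over all genes was 12.24 in WT and 12.25 in mir163.

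The comparison of mir163 with WT asks which transcripts differ in seedlings of the mutant. The transcript of the mutated locus, MIR163 (AT1G66725), stood at an FPKM of 20.5 in WT and 0.0726 in mir163. The gene lies on chromosome 1, positions 24884066 to 24884396 on the plus strand of TAIR10.1, and is annotated as a microRNA gene. Its mature product, TTGAAGAGGACTTGGAACTTCGAT, is 24 bases long and matches positions 24884359 to 24884382. In the authors' deposited table this difference had a log2 fold change of -8.14 and a p of 0.180, so MIR163 did not pass the threshold.

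Of the 6 miR163 targets, 3 were analysed here, and the 2 with enough expression to be tested rose in mir163. PXMT1 (AT1G66700), a SABATH methyltransferase that can methylate paraxanthine, went from an FPKM of 1.32 to 47.6, a 36.1-fold rise. AT1G15125, another methyltransferase of this family, went from 9.99 to 33.3, or 3.33-fold. With the authors' p-values adjusted over the list alone (Benjamini-Hochberg, 2 genes tested), the adjusted p was 0.0001 for PXMT1 and 0.0026 for AT1G15125. FAMT (AT3G44860), which methylates farnesoic acid, was near the lower limit in both genotypes, with an FPKM of 0.745 in WT and 0.723 in mir163. The others, AT1G66690, AT1G66720 and AT3G44870, were not analysed here, which was not a choice made on their values. PXMT1 and AT1G66690 are paralogs of 1 family that carry the same miR163 site sequence, and whether the authors' counting shared reads between them was not tested, so the level of PXMT1 is uncertain to that extent.

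The miR163 site of PXMT1 is ATCGAGTTCCAAGTCCTCTTCAA, on chromosome 1 at positions 24874307 to 24874329 of TAIR10.1, minus strand. It lies in the coding sequence, in exon 2 of 3, and differs from a perfect match to the mature sequence by 1 missing base. The site of FAMT lies on chromosome 3 at positions 16380056 to 16380078, plus strand, also in coding sequence, and has 3 differences. Outside the methyltransferases, FDM1, AT1G64840 and DEG2 each had a site with 4 differences and were in the table. Their FPKM in WT and mir163 was 7.87 and 8.66 for FDM1, 9.87 and 9.70 for AT1G64840, and 80.6 and 80.9 for DEG2. The authors' deposited table gave these 3 genes p-values of 0.738, 0.953 and 0.989. AT1G15125 had no site within 4 differences in its annotated transcripts.

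The other SABATH methyltransferases did not move with PXMT1. Of 10 tested, 5 had a higher and 5 a lower value in mir163, and 0 passed the threshold when adjusted over the list alone. The most abundant, AT5G37990 and AT5G38020, had FPKM values of 27.5 and 19.5 in WT against 25.4 and 17.2 in mir163. Among the 20 annotated neighbours of MIR163, 10 on each side, 9 were tested and 1, PXMT1, rose, with an adjusted p over the list alone of 0.00045. Of the others, 7 had a lower value, and the most abundant, CLPP3, a subunit of the chloroplast Clp protease, stood at 84.2 in WT and 92.0 in mir163. Targets of other microRNAs gave 0 of 26 past the threshold. AGO1, the main slicer of microRNA targets, stood at 77.6 and 67.8, and CSD2, a chloroplast superoxide dismutase, at 87.5 and 69.3.

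**Figure D1:**
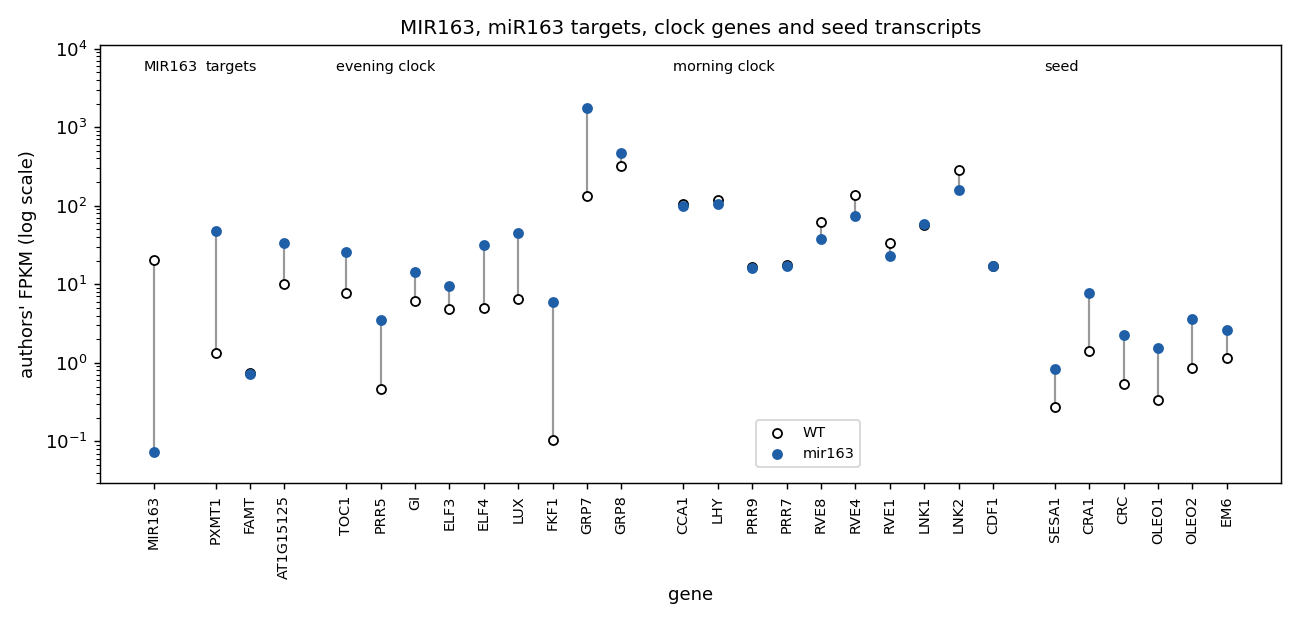
The authors' FPKM (log scale) of MIR163, measured miR163 targets, clock genes and seed transcripts, with 1 open circle for WT and 1 filled circle for mir163 per gene and a line joining them. MIR163 stands at 20.5 and 0.0726, PXMT1 at 1.32 and 47.6, and each of the 9 evening-phased clock genes lies higher in mir163.

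Evening-phased genes of the circadian clock stood higher in mir163 as a group. All 9 members had a higher value, and 7 rose when adjusted over the list alone, without correction across the 24 lists. The adjusted p-values below are of this kind. No member passed when adjusted over all genes, where ELF3 and LUX had an adjusted p of 0.9996. PRR5 and FKF1, at an FPKM under 1 in WT, were tested only through their mir163 values, so the filter fixed their direction. PRR5, a pseudo-response regulator that represses morning genes, went from an FPKM of 0.469 to 3.47 (7.41-fold, adjusted p 0.000225). The evening complex, which binds promoters at dusk, had higher values in all 3 subunits. ELF4 went from 4.99 to 31.4 (6.30-fold, adjusted p 0.000225), LUX from 6.59 to 44.7 (6.78-fold, adjusted p 0.0033) and ELF3 from 4.87 to 9.43 (1.94-fold, adjusted p 0.0472). FKF1, a blue-light receptor of the flowering pathway, went from 0.105 to 5.90 with an adjusted p of 0.00394. TOC1, the core evening repressor, went from 7.72 to 26.0 (3.38-fold, adjusted p 0.00558), and GI from 6.06 to 14.3 (2.36-fold, adjusted p 0.0268). The RNA-binding proteins GRP7 and GRP8 did not pass, with FPKM values of 132 and 323 in WT against 1737 and 470 in mir163. The median log2 change of the list was 1.63, at percentile 100 of 10000 random lists matched on expression, with 2.63 at a pseudocount of 0.1 and 1.09 at a pseudocount of 5.

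Morning-phased clock genes did not pass in any of 10 cases, although 9 had a lower value in mir163. Their median log2 change was -0.11, at percentile 5.84. LNK2, a coactivator of evening genes, had the highest level, at 287 in WT and 160 in mir163. LHY, a central morning repressor, was at 117 and 107, and its partner CCA1 at 105 and 98.4.

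Transcripts of seed storage and late embryogenesis were low in both genotypes and higher in mir163. All 5 tested members had a higher value, with a median log2 change of 1.07 at percentile 100, and 1 rose when adjusted over the list alone. This was CRA1, the cruciferin storage globulin, which went from an FPKM of 1.43 to 7.71 (5.38-fold, adjusted p 0.00625). OLEO2, an oil-body coat protein, stood at 0.861 in WT and 4.18 times that in mir163 and did not pass. The late embryogenesis protein EM6 was at 1.17 and 2.60. At these low levels the median depended on the pseudocount, at 1.91 with 0.1 and 0.39 with 5. Only 2 of the 5 reached an FPKM of 1 in WT. The rest were tested only through their mir163 values, so the filter fixed their direction.

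Photosynthesis and light genes mostly had lower FPKM values in mir163, and 0 passed the threshold. Of 22 genes for light-harvesting proteins and the small subunit of Rubisco, 21 had a lower value, with a median log2 change of -0.30 at percentile 0. Quantile normalization moved that median to -0.03 at percentile 17.0, so its place outside the central 95% depended on the scaling. RBCS1A stood at 18310 in WT and 15342 in mir163, and LHCB1.3 at 12577 and 11412. Light signalling genes had a median of -0.16 at percentile 0.05, with 15 of 20 lower. Here the most abundant were ELIP2 and ELIP1, photoprotective proteins induced by strong light, at 244 and 138 in WT against 225 and 121 in mir163. Auxin response genes had a median of -0.19 at percentile 0.06, with 0 of 16 past the threshold. The auxin repressors IAA7 and IAA17 were at 190 and 137 in WT and 166 and 105 in mir163. Flavonoid and anthocyanin genes had a median of -0.11 at percentile 2.44, with 0 of 16 past the threshold, CHS at 301 and 257 and C4H at 274 and 237.

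Cell division genes lay higher in mir163 in 10 of 10 cases, with a median log2 change of 0.35 at percentile 100 and 0 past the threshold. CYCD3;1, a cyclin of the G1 phase, was at 20.9 in WT and 29.0 in mir163, and PCNA1, the replication clamp, at 18.1 and 25.4. Jasmonate genes had a median of 0.15 at percentile 99.7, and the lowest adjusted p over the list alone was 0.0779. The jasmonate synthesis enzyme AOC2 was at 28.5 in WT and 97.2 in mir163, and AOS at 67.3 and 95.8. Heat shock genes had a median of 0.22 at percentile 99.99, with 11 of 17 higher, 6 lower and 0 past the threshold. HSP70 stood at 359 and 478 and MBF1C, a coactivator of the heat response, at 234 and 317. The list's lowest p-values in the authors' deposited table belonged to small heat shock proteins with lower values, AT1G53540 at 22.0 and 10.2 (p 0.0183) and AT4G10250 at 2.25 and 0.453 (p 0.0282). Genes of abscisic acid, cold and drought had a median of 0.15 at percentile 97.8, with 0 of 10 past the threshold. COR47, a dehydrin, was at 208 and 272, and RD22 at 225 and 216.

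Metabolic and nutrient lists gave 0 members past the threshold. Aliphatic glucosinolate genes had a median log2 change of 0.14 at percentile 99.7 over 17 genes, with GSTU20 at 201 in WT and 222 in mir163 and IPMI2 at 87.1 and 101. Indole glucosinolate genes had a median of 0.0034 at percentile 48.1, with CYP83B1 at 112 and 122 and SUR1 at 66.1 and 68.0. Scaling by median ratios turned the sign of that median. Iron deficiency genes had a median of 0.11 at percentile 98.6, with the peptides IMA3 and IMA2 at 330 and 257 in WT against 402 and 343. Phosphate starvation genes had a median of 0.11 at percentile 96.4, with SQD1 at 71.9 and 73.5 and the transporter PHT1;1 at 48.0 and 52.1.

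Lists of salicylic acid, ethylene, gibberellin, touch and root genes lay within the central 95% of the matched random lists, with 0 members past the threshold. Salicylic acid and systemic defence genes had a median log2 change of 0.03 at percentile 59.0, with the defence regulator NPR1 at 9.75 in WT and 11.2 in mir163 and SARD4 at 9.56 and 12.2. Ethylene genes had a median of -0.05 at percentile 20.3, with PR4 at 117 and 139. Gibberellin genes had a median of 0.07 at percentile 87.6, with GASA1 at 1418 and 1253 and GASA6 at 455 and 332. Touch and rapid stress genes had a median of 0.07 at percentile 82.8, with the calmodulin-like TCH3 at 105 and 64.9 and TCH2 at 88.0 and 83.0. Root hair and endodermis markers had a median of -0.09 at percentile 4, with PRP3 at 84.8 and 84.6 and CASP1 at 56.6 and 50.2.

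For the lists built around miR163, the other SABATH methyltransferases had a median of -0.02 at percentile 30.9, targets of other microRNAs -0.07 at percentile 3.28, neighbours of MIR163 -0.17 at percentile 1.43, and the 2 miR163 targets 3.02 at percentile 100.

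**Figure D2:**
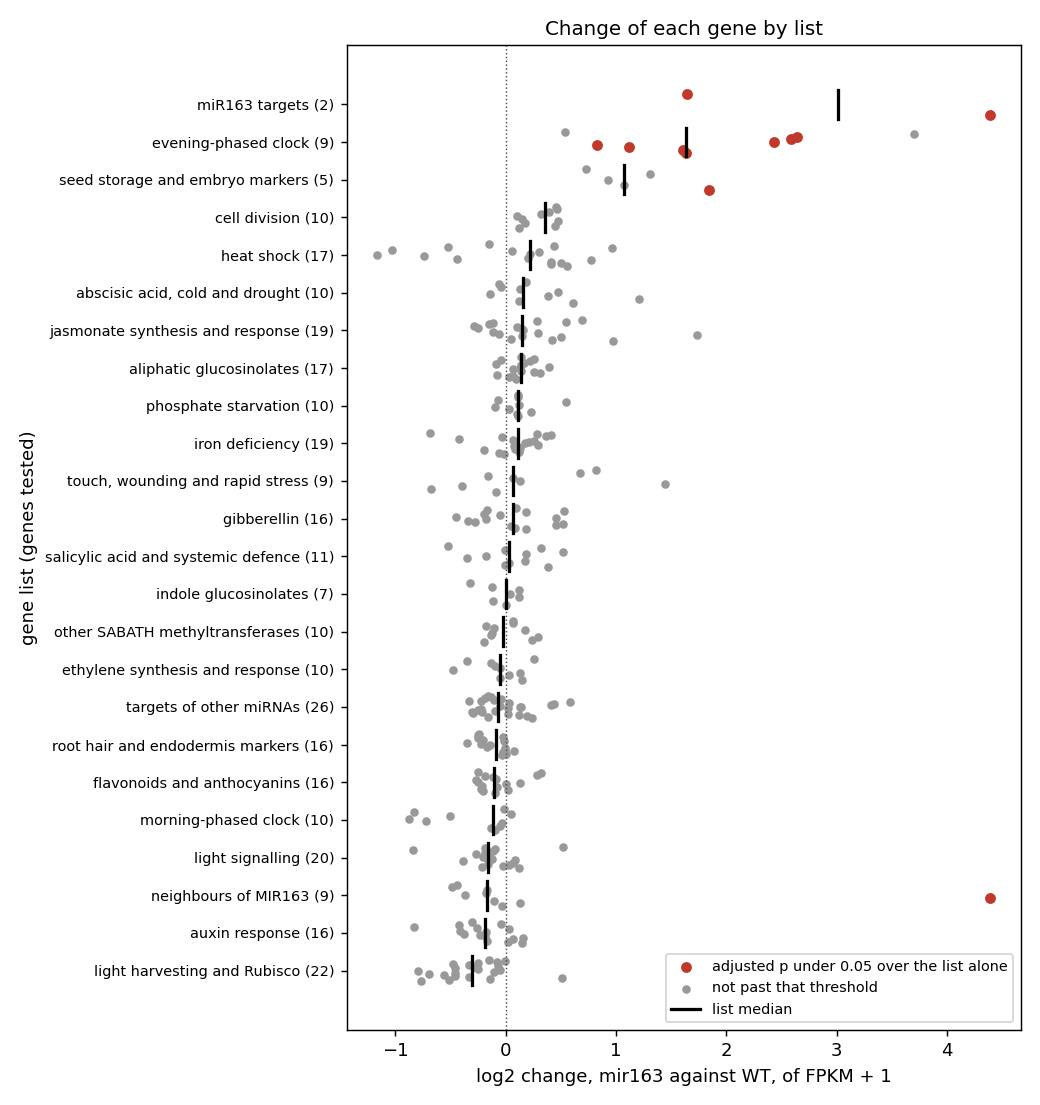
Log2 change of FPKM + 1, mir163 against WT (horizontal axis), for each tested gene of the 24 lists (vertical axis, number of genes tested in brackets). Points are genes, red where the adjusted p over the list alone is under 0.05, and black bars are list medians; the red points lie in the lists of miR163 targets, evening-phased clock, seed storage and neighbours of MIR163.

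Of the 24 lists, 14 had a median outside the central 95% of their random lists, 9 high and 5 low, where 1.2 would be expected of lists of unrelated genes. Genes of one pathway vary together, so these percentiles describe the deposited values and are not tests against replicate error. Among 316 list members tested, 11 passed the threshold adjusted over the list alone, counting PXMT1 in each of its lists. These calls were not corrected across the 24 lists.

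Over all 19264 genes tested, the authors' p-values adjusted by Benjamini-Hochberg called 0 genes higher and 0 lower in mir163 at 0.05. The lowest adjusted p was 0.0876. After all p-values were rescaled to the median of uniform ones, an alternative chosen after seeing the data, 375 genes were called higher and 265 lower. At an unadjusted p under 0.05 the authors' deposited table held 129 genes higher and 63 lower among those tested. Uniform p-values would give 963 genes under 0.05, and the median p was 0.768. The lowest p in the authors' deposited table, 5e-05, was shared by 11 of the genes tested, and 20 genes would be needed at that value for an adjusted p under 0.05.

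The genes with the largest higher values in mir163 at an unadjusted p under 0.05 were ranked by the change in log2(FPKM + 1), which gives less weight to low genes than the plain ratio does. The first was AT5G62360, of the family of pectin methylesterase and invertase inhibitors, at an FPKM of 1.15 in WT and 54.4 in mir163, a ratio of 47.2. It was followed by PXMT1 and by JMJD5, a jumonji-domain protein with a role in the clock, at 1.53 and 32.8. COR27, a cold-regulated repressor of clock genes, was at 0.449 and 17.3, and COL9, a CONSTANS-like regulator of flowering, stood at 1.65 in WT and 9.50 times that in mir163. AT1G56300, which has a DnaJ chaperone domain, was at 2.94 and 44.9, AT3G62550 at 5.78 and 49.9, and AT2G38465 at 0.547 and 8.12. FKF1 and LUX, of the evening-phased clock list, completed the 10. By plain ratio FKF1, at 56.0, would come first among the genes not listed at 0 in WT. BOA, a close homologue of LUX, shared the lowest p and was at 1.06 and 8.32.

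On the same scale, the largest lower values in mir163 were led by AT3G01345, at an FPKM of 317 in WT and 0.626 in mir163, a ratio of 506 between WT and mir163. MRD1 stood at 52.1 and 1.25, and ASN1, the asparagine synthetase induced in darkness and by sugar starvation, at 223 and 16.8. AT3G43850 was at 5.78 and 0.401. AT4G09649, RTFL18, a small signalling peptide, and MIR169k were at 117, 44.3 and 7.62 in WT and are listed at 0 in mir163. The spliceosomal RNA U1.5 was at 341 and 58.3, the small nucleolar RNA AT4G39364 at 1597 and 305, and the chloroplast-encoded photosystem subunit ATCG00690 at 1075 and 200.5. None of these 20 genes passed the threshold over all genes, and the 2 sets were ranked after it was known that none would. Among those with lower values, AT4G09649, MIR169k, U1.5 and AT4G39364 have annotated lengths of only 138, 213, 165 and 122 bases. Whether short length made their FPKM unstable was not tested.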

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

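The rescaling of p-values was chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the deposited table gives 1 value per genotype. For the same reason leaving out each library, library weights, camera, fry and splits of the libraries were not run, and the authors' p-values cannot be recomputed under another scaling or pseudocount. With the authors' p-values adjusted by Benjamini-Hochberg, 0 genes were called higher or lower with no filter and with a minimum FPKM of 5, where the lowest adjusted p was 0.0907 and 0.0925. At an unadjusted p under 0.05 there were 131 higher and 66 lower with no filter, 101 and 50 at the stricter minimum, and 122 and 59 with at least a 2-fold change. After dividing the chi-square values of all genes by 1 factor of 0.192, so that their median was that of uniform p-values, 375 genes were called higher and 265 lower. That factor assumes that most genes do not differ, so the count of 0 depends on how the authors' p-values are scaled. The 2 miR163 targets passed under both filters. Of the evening clock genes, 7 passed with no filter and 6 at the stricter minimum, which tests fewer genes. With no filter the evening clock genes tested were unchanged, as were the 2 targets at the stricter minimum, so those counts could not move. Between 12 and 14 lists lay outside the central 95% over all settings. Each of 19 named genes kept its direction under 4 scalings and pseudocounts, in 76 of 76 comparisons. A pseudocount cannot turn the sign of a gene, and median-ratio scaling divided by only 1.005. For these genes, therefore, only quantile normalization could have reversed a direction. List medians kept their direction in 119 of 120 comparisons. The exception was indole glucosinolates, at -0.0038 with median-ratio scaling. Pseudocounts leave the sign of each member as it is, and median-ratio scaling hardly moved values. Most of these comparisons could therefore seldom have reversed a median. Sizes were less stable: 18 of the 120 list medians, in 11 of 30 lists, moved by over 1.5 times. Light harvesting and Rubisco went from -0.30 to -0.03 with quantile normalization; seed storage ran from 0.39 to 1.91, further seed transcripts from 0.17 to 0.97 and evening clock genes from 1.09 to 2.63 between pseudocounts of 5 and 0.1. Unknown depth limits genes with low FPKM most.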

Other observations

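The search for miR163 sites in clock mRNAs, the lists of starch breakdown and sugar starvation genes and the look at chloroplast genes were chosen after values had been seen. The other tests were set before their own results. However, the lists of further dusk-phased, dawn-phased and seed genes were not fixed before the data were examined. They are therefore not independent evidence. Enzymes of leaf starch breakdown stood higher in mir163. Of 12 tested, 11 had a higher value, with a median log2 change of 0.43 at percentile 100, and 3 passed when adjusted over the list alone. These were ISA3, a debranching enzyme, from an FPKM of 3.09 to 8.01, PHS2, a cytosolic phosphorylase, from 9.53 to 30.3, and DPE1, a disproportionating enzyme, from 5.03 to 15.5, each at an adjusted p of 0.0488. Genes induced by sugar starvation and darkness lay on the other side, with 13 of 13 lower, a median of -1.23 at percentile 0, and 0 past the threshold. Besides ASN1, the senescence-associated SEN1 was at 237 in WT and 97.8 in mir163, THA1, a threonine aldolase, at 16.6 and 4.70, and MCCA, of leucine breakdown, at 29.2 and 10.5. Some members of both lists were known to have a low p when the lists were drawn up, so their counts are not independent evidence. A difference in time of day at harvest, weighed below for the clock genes, may also have moved these lists, which was not tested. The lists therefore do not show a separate effect of the genotype on metabolism.

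Most chloroplast-encoded transcripts had lower values in mir163, and 0 passed when adjusted over these genes alone. Of 96 tested, 78 had a lower and 18 a higher value, and the median log2 change was -0.36 at percentile 0. Their share of all FPKM was 13.2% in WT and 9.51% in mir163. Of the difference in summed FPKM, however, 6 abundant transcripts made up 90.8%. These were led by ATCG01020 at 49109 and 28746 and included ATCG00030, at 5615 in WT and listed at 0 in mir163. The lowest p among the 6 in the authors' deposited table was 0.0998. Whether short length made the FPKM of these 6 unstable was not tested. Higher values included ATCG00590 at 62.4 and 412 and ATCG00570 at 136 and 469. The authors' deposited table gave 7 of them a p under 0.05, each lower, among them the photosystem I genes ATCG00340 (42.1 and 12.8) and ATCG00350 (30.9 and 9.01) and the cytochrome gene ATCG00720 (31.9 and 10.8). The 30 mitochondrial genes tested had a median of 0.13, and 0 had such a p. The chloroplast gene ATCG00490, for the large subunit of Rubisco, was at only 43.1 in WT and 27.3 in mir163. RBCS1A, for the small subunit, was at 18310 and 15342. How evenly the libraries captured chloroplast transcripts was not tested, so these values do not show lower chloroplast expression in mir163.

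The evening clock genes were higher in mir163 while 9 of 10 morning clock genes had a lower value and 0 passed, with ratios of mir163 to WT from 0.541 for RVE4 to 1.04 for LNK1, and 0.937 for CCA1. Whether miR163 cleaving these mRNAs itself contributes stays open: 0 of 9 evening clock mRNAs held a miR163 site within 4 differences, but the same search missed 1 of the 2 tested targets, AT1G15125. A difference in time of day at harvest may account for the pattern, but the morning-phased list gives it little weight. That list, fixed before the data were examined, lay at percentile 5.84, which is not under the limit of 2.5. Ratios of mir163 to WT were 0.913 for LHY, 0.959 for PRR9, 0.973 for PRR7 and 0.985 for CDF1. Lower ratios were found for RVE1 (0.695), RVE8 (0.599) and LNK2 (0.559). In 4 further dusk-phased genes the median log2 change was 1.76 at percentile 100 (1.02 with a pseudocount of 5). COR27 and AT4G33980 (0.109 in WT, 4.99 in mir163) led them. Both were tested only through their mir163 values, so the filter fixed their direction. Of 11 further dawn-phased genes, 9 were lower, with a median of -0.22 at percentile 0.34. Of the 4 dusk-phased genes, CHE was at -0.09 on the log2 scale, from an FPKM of 53.2 in WT. CAT3 was at 462 in WT and 976 in mir163, with a p of 0.462 in the authors' deposited table. An indirect effect of the genotype on the clock stays open and untested. It could move dusk-phased and dawn-phased genes in the same way, so these lists cannot separate it from a difference in harvest time. The labels used here give no harvest time, and the values are 1 per genotype.

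Seed storage transcripts were higher in mir163, and seed or embryo tissue among the mutant seedlings may account for this. A second set of seed transcripts had a median log2 change of 0.52 at percentile 100 (0.17 at percentile 99.96 with a pseudocount of 5), with 5 of 6 higher and 0 past the threshold. Its most abundant member, LEA18, was at 3.33 in WT and 10.6 in mir163, and PER1, a seed peroxiredoxin, at 1.39 and 3.95. WT seedlings also expressed these genes at an FPKM of 1 or more, 2 of 5 in the first set and 3 of 6 in the second. The others in both sets were tested only through their mir163 values, so the filter fixed their direction. A stronger response to abscisic acid in the mutant stays open. Of 10 genes of the abscisic acid, cold and drought list, 7 had a higher and 3 a lower value, and 0 passed the threshold. The median log2 change was 0.15 at percentile 97.8. RAB18, with the list's lowest p in the authors' deposited table (0.013), was at 8.64 in WT and 21.2 in mir163. Ratios of mir163 to WT ran from 0.881 for KIN1 to 3.17 for ABI5, which was tested only through its mir163 value.

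Many of the largest ratios had no low p, MIR163 among them. Of 53 tested genes with at least an 8-fold ratio or listed at 0 in a genotype, 30 had a p of 0.05 or more. Short transcripts with unstable FPKM are a candidate explanation. The 30 had a median annotated gene length, introns included, of 473 bases against 1639 for the 23 genes with a lower p. That is a ratio of 0.289, over the 50 genes with a length. Under 400 bases there were 12 genes among the 30 and 3 among the 23. A real loss of the MIR163 transcript in the mutant is not excluded by its p, and GRP7, also among the 30, belongs to the evening clock genes weighed before.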
